A study of Mus musculus with 4 samples.

How the data were processed

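Messenger RNA was sequenced from macrophages grown out of mouse blood. Per the labels' protocols, blood from C57BL/6J mice aged 10 to 16 weeks (60 mice, 1 ml each) was pooled, monocytes were selected for CD11b, and the cells were kept for 6 or 7 days with 30 ng/ml M-CSF. Activation was with LPS at 500 ng/ml and IFNγ at 20 ng/ml. The strain label of the peptide samples reads C57BL/7J and was taken as the same strain as the others. The libraries were made with the NEXTflex Rapid Directional mRNA-Seq kit, per the labels' protocols. Samples were grouped by their titles into M-CSF alone (1 library), classically activated macrophages (CAM, 1 library) and CAM treated with the peptide mML56 (2 libraries, called library 1 and library 2 here by the numbers of their columns). The labels do not say what the suffix in the title of one peptide sample marks. The columns of the M-CSF and CAM libraries carry the numbers 2 and 1, which no label explains. The labels also do not say that the libraries came from separate cultures. The p-values of single genes therefore measure only the spread between the 2 peptide libraries, which may be technical.

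The authors deposited estimated counts per gene, unscaled and partly fractional (61.5% to 69.5% of a library's values were whole numbers). Per the submitters' processing notes, kallisto and StringTie were used with the genome build mm10. The version of kallisto, the annotation release, the strand setting and the way transcripts were summed to genes are not given in the sources used here. Gene symbols, Ensembl identifiers and coordinates were taken from the deposited table. GENCODE M21, on the same assembly, held 32207 of the 32617 genes, and 28282 of these (87.8%) had the same chromosome, start and end; it was used for GC content, and for the overlap of genes with each other. Some genes that most cells express were listed at 0 in single libraries, so an exact 0 in this table can be a failed estimate. Such genes are described as listed at 0, with the value in the group compared. Values above 0 may be too low as well. Actb and Rplp0, which most cells express, were chosen after their values were seen. Before TMM scaling Actb stood at 92.2 (M-CSF), 39.7 (CAM), 67.9 and 109 CPM (peptide libraries 1 and 2). Rplp0 stood at 0.65, 17.8, 1.73 and 1.4 CPM in the same order. How many genes this affects was not tested.

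Estimated counts were rounded to whole numbers. The totals were 12414713 (M-CSF), 10334062 (CAM), 12842750 (peptide library 1) and 12119505 (peptide library 2), and every comparison covers genes detectable at that depth. Of the genes in the table, 13199 had no count in any library, and filterByExpr in edgeR 4.0.16 (R 4.3.3) kept 14104 for testing. Libraries were scaled by TMM, with factors of 1.24, 0.894, 0.906 and 0.993. CPM values are counts scaled to the TMM-adjusted library size. The test was edgeR's quasi-likelihood F test (estimateDisp, glmQLFit, glmQLFTest) on all 4 libraries in 3 groups with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. No label stated a test. Because 2 of the groups had 1 library, the spread came from the pair of peptide libraries with 1 residual degree of freedom, moderated across genes (prior degrees of freedom 11.8, common dispersion 0.026, biological coefficient of variation 0.161), and the lone libraries were assumed to vary like the peptide libraries. Log2 fold changes carry edgeR's prior count of 0.125. Their standard errors are the fold change divided by the square root of F. Genes that differed by at least 2-fold were also counted without a test.

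Before the data were examined, 32 gene lists, the comparisons, the tests, the alternatives and the rule for named genes were fixed. A list's result is the number of tested members that rose or fell past the threshold over all genes and adjusted over the list alone, the median log2 fold change, and camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera with the preset correlation takes genes as its units, so its p-values measure spread between genes and not between libraries. With an estimated correlation it tests each list on 1 residual degree of freedom, so hardly any list could pass. Medians were also placed among 10000 random lists matched on mean expression in 20 bins. A member at 0 in a group has a fitted fold change that depends on the prior count, so medians that such members move were also computed with them at the bound that a floor of 3 counts per library gives. The rule named, for CAM against M-CSF and for peptide against CAM, the 10 genes with the largest and the 10 with the smallest log2 fold change among symbol-named genes (no Gm, Rik or pseudogene models) past the threshold with at least 10 CPM in the higher group, both peptide libraries lying on the same side of CAM. It also named Ninj1 and up to 2 members of each list in each direction with at least 1 CPM in the higher group. Genes named outside the rule are said to have been chosen after their values were seen. An item that the rule named is not reported here. H2-K1, H2-D1 and the H2-Q genes, Gbp2 and Gbp2b, Serpina3f and Serpina3g, Hspa1a and Hspa1b, and ribosomal proteins and other genes with many pseudogenes have near-identical copies, between which the upstream quantification could have split reads, so their values are uncertain.

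Peptide libraries were compared with each other by a chi-square over genes and by Pearson's r of log2 CPM. The covariance of the activation effect with the peptide effect was set beside 100 simulations of 4 unchanged libraries, because both effects use the same CAM library with opposite sign. Alternatives were DESeq2 size factors, library size only, no filter on low counts, a prior count of 2, robust empirical Bayes, only the libraries of the 2 groups compared, DESeq2's Wald test (version 1.42.0), leaving out each peptide library, and an estimated correlation in camera. Chosen after seeing the data were a fit without Lars2 and Gm15662, an offset per library for transcript length and GC content (mgcv 1.9.3, on the 13999 tested genes with a GC value), thinning to the shallowest library, and a block on the column numbers. Length and GC content together explained 1.03% (M-CSF), 6.04% (CAM), 2.23% and 2.73% (peptide) of the deviance. The test was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For CAM against M-CSF, on 13421 genes, it recovered 29 and 70 of them, with 8 false calls among 107. For peptide against CAM, on 13445 genes, it recovered 39 and 84, with 11 false calls among 134. For peptide against M-CSF, on 13462 genes, it recovered 39 and 82, with 14 false calls among 135. In each comparison the share of false calls was above the threshold of the adjustment. All simulated libraries varied like the peptide pair, and far fewer genes were changed than the data called. The simulation therefore cannot show how many calls are false if the lone CAM and M-CSF libraries varied more than that pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.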

Results

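Gene expression was measured by mRNA sequencing in macrophages grown from mouse blood monocytes. M-CSF, the growth factor that drives monocytes to become macrophages, was present in every culture. The 4 libraries formed 3 groups. M-CSF macrophages (1 library) received no further stimulus. Classically activated macrophages (CAM, 1 library) were stimulated with LPS, a bacterial cell wall component, and IFNγ, a cytokine made by T and NK cells. Peptide-treated CAM (2 libraries) also received mML56, a peptide of residues 1 to 56 of Ninj1 that mimics the soluble form of that protein. Ninj1 is a cell-surface adhesion protein that also ruptures the plasma membrane in lytic cell death. The labels give an anti-inflammatory role of Ninj1 as the subject. Estimated counts per library totalled 12414713 in M-CSF macrophages, 10334062 in CAM, and 12842750 and 12119505 in peptide libraries 1 and 2, with counts in 17446, 14772, 16653 and 16916 genes.

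The peptide libraries resembled each other far more than either resembled CAM. Of 7376 genes at a mean of at least 10 CPM, 84 (1.14%) lay at least 2-fold apart between the peptide libraries, against 24.7% and 23.3% between CAM and either of them and 38.7% between M-CSF and CAM. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.978 within the peptide pair, 0.898 and 0.897 with CAM, and 0.777 between M-CSF and CAM. The peptide pair still differed by more than sampling noise (chi-square 205134 on 14015 degrees of freedom), and the libraries were kept as 2 samples, though repeat preparations of 1 culture could also differ by more than that noise. Lars2, a mitochondrial leucyl-tRNA synthetase, and the gene model Gm15662 were named after their values were seen, as the genes with the most counts. Together they took 6.40% of counts in M-CSF, 14.2% in CAM, and 10.5% and 7.79% in the peptide libraries. Mitochondrially encoded genes took 6.08%, 1.63%, 1.32% and 1.01%. The share of Lars2 and Gm15662 was highest in the lone CAM library, which both main comparisons use. Whether the reads counted for Lars2 and Gm15662 came from transcripts of these genes was not tested. The 95% Wilson intervals of these shares reached at most 0.021 percentage points to either side and cover counting error only.

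The comparison of CAM with M-CSF macrophages asked what activation did to these cells. Genes of inflammatory mediators went from near absence to some of the highest levels measured. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis (ENSMUSG00000032487, mm10 chromosome 1, 150100031 to 150108227), stood at 0.972 CPM in M-CSF and 17770 CPM in CAM, a log2 fold change of 14.14 (SE 0.523, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.15e-10). Nos2, which makes nitric oxide (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), went from 0.1945 CPM, a level of few counts, to 15950 CPM. Macrophage genes such as Cebpa, a transcription factor of myeloid cells, fell, from 18.3 to 0.65 CPM (log2 fold change -4.80, SE 0.446). Each of these groups had 1 library, so the values have no SD, and the test borrowed its spread from the peptide libraries.

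Of 20 tested cytokine and mediator genes, 18 rose on activation and none fell, and the counts adjusted over the list alone were 18 and 0. Il12b, the p40 subunit shared by IL-12 and IL-23 (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033), was listed at 0 in M-CSF and at 719.6 CPM in CAM, while Il18 was at 6.42 and 6.39 CPM. The median log2 fold change was 8.51, or 6.2 with the 6 members at 0 set at their bound (camera adjusted p = 8.23e-10, and adjusted p = 0.733 with an estimated correlation). Tnf, a member of the list named after its values were seen, was listed at 0 in all 4 libraries and was not tested. Among 17 chemokines 14 rose and 3 fell, the same adjusted over the list alone, with a median of 5.61 (camera adjusted p = 5.08e-06, and adjusted p = 0.733 with an estimated correlation). Cxcl9, which attracts T cells, went from 1.43 to 4057 CPM. Among 20 NF-kB feedback and target genes 18 rose and none fell, the same adjusted over the list alone, with a median of 2.4 (camera adjusted p = 2.94e-08, and adjusted p = 0.733 with an estimated correlation), and Cd40 had a log2 fold change of 7.23.

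Genes that interferons switch on rose almost as a block. All 24 tested IFNγ-induced GTPases and regulators rose, with a median of 6.65, and 32 of 33 type I interferon-stimulated genes rose, with a median of 3.37; none fell in either list, and the counts adjusted over the list alone were the same. Camera gave adjusted p = 4.62e-15 for each, and adjusted p = 0.733 with an estimated correlation. Oasl1, an antiviral protein, went from 2.46 to 584.6 CPM, and Gbp2b was listed at 0 in M-CSF and at 60.3 CPM in CAM. For antigen presentation, 8 of 9 MHC class II genes rose and none fell (median 3.64, or 3.55 with the member at 0 at its bound), and 16 of 18 class I genes rose while 1, H2-K1, fell (median 1.93). Both pairs of counts were the same adjusted over the list alone. The camera values were adjusted p = 0.000749 and 8.03e-06, and adjusted p = 0.733 with an estimated correlation. H2-K1 stood at 529.5 CPM in M-CSF and 273.1 in CAM, a value that near-identical class I genes make uncertain.

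All 24 glycolysis and hypoxia-response genes rose (also 24 adjusted over the list alone), with a median of 3.26 (camera adjusted p = 2.97e-11, and adjusted p = 0.733 with an estimated correlation), while 12 of 13 mitochondrially encoded genes fell (also 12 adjusted over the list alone), with a median of -1.66 (camera adjusted p = 0.000749, and adjusted p = 0.733 with an estimated correlation). mt-Nd3, a subunit of respiratory complex I, went from 262.7 to 29.4 CPM. Oxidative stress genes rose in 16 of 21 cases and fell in 3 (12 and 5 with library size only), with a median of 1.48, and Slc7a11, the cystine transporter, went from 11.9 to 1772 CPM (log2 fold change 7.22, SE 0.264). Heat shock genes rose in 8 of 12 cases and fell in 1, with a median of 1.79; Hspa1a had the largest rise, at a log2 value of 8.07, and Hspa8 fell by 2.36. Camera gave adjusted p = 0.000497 and 0.00471 for these lists, and adjusted p = 0.733 with an estimated correlation, and their counts adjusted over the list alone were the same.

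Macrophage identity genes fell in 13 of 21 cases and rose in 2, with a median of -1.98, and lysosome and phagocytosis genes fell in 15 of 27 and rose in 4, with a median of -0.80. Gas6, a bridging molecule for the uptake of dying cells, had a log2 fold change of -5.28, and Cd68, a lysosomal membrane protein, went from 13.4 to 1.19 CPM. Adjusted over the list alone these counts were the same, though with library size only lysosome genes fell in 19 cases and rose in 1; camera gave adjusted p = 0.0284 and 0.038, and adjusted p = 0.733 with an estimated correlation, and without a filter on low counts the lysosome list no longer passed (adjusted p = 0.094). Ninj1, adhesion and metalloproteinase genes rose in 14 of 29 cases and fell in 3 (median 0.81), led by Mmp13, a collagenase, at 7.00 and 575.7 CPM. Inflammasome and lytic death genes rose in 11 of 18 and fell in 3 (median 0.89), with Mlkl, the pore former of necroptosis, at a log2 fold change of 4.55. Their counts were the same adjusted over the list alone, but 9 and 5 for each with library size only as the scaling (medians 0.33 and 0.416), and camera gave adjusted p = 0.00694 and 0.0251, and adjusted p = 0.733 with an estimated correlation. Ninj1 itself (ENSMUSG00000037966, chromosome 13, 49187485 to 49196244) stood at 40.6 and 44.6 CPM, a log2 fold change of 0.14 (SE 0.21) that was not past the threshold (edgeR adjusted p = 0.625); with the offset for length and GC content it was 0.65 (adjusted p = 0.0234).

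The remaining lists went both ways or had few members past the threshold, and none passed camera. Counts that rose and fell were 8 and 8 of 20 for alternative activation, where Arg1 rose by a log2 value of 7.12, and 3 and 9 of 27 for oxidative phosphorylation (1 and 14 with library size only). They were 4 and 10 of 22 for lipid handling (4 and 11 adjusted over the list alone), with Pltp, a phospholipid transfer protein, at 105.7 and 2.17 CPM, and 5 and 10 of 21 for PI3K, insulin and FoxO targets (5 and 11 adjusted over the list alone). They were 4 and 3 of 18 for cholesterol synthesis (3 and 2 adjusted over the list alone), 7 and 4 of 25 for cell cycle (7 and 5) and 8 and 2 of 21 for unfolded protein stress (9 and 2), but 2 and 6, 3 and 7, and 5 and 7 with library size only as the scaling. They were 9 and 4 of 18 for immediate early genes, and 1 and 1 of 7 for histones. Among markers of other blood and tissue cells, neutrophil markers rose in 2 of 4 cases (1 with library size only, and 1 with the offset). T and NK markers rose in 3 and fell in 1 of 6 (1 and 1 with library size only), dendritic cell markers rose in 3 of 7, and fibroblast and endothelial markers in 1 of 10. B cell markers fell in 1 of 4, platelet markers in 3 of 6 (1 rose and 3 fell adjusted over the list alone), basophil and mast cell markers in 1 of 2, and erythroid markers in 0 of 2. Ighm, the IgM heavy chain, went from 110.3 to 0.1083 CPM, and Pf4, a platelet chemokine, from 74.3 to 2.06 CPM.

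Besides Nos2, Il12b, Ptgs2 and Gbp2b, the largest rises by the fixed rule were in genes listed at 0 in M-CSF. In CAM they stood, among others, at 320.6 CPM for Upp1, a uridine phosphorylase, 263.1 for Serpina3f, 112.3 for Serpina3g, 81.9 for Mcl1, an anti-apoptotic protein at 12.3 and 2.58 CPM with the peptide, and 75.1 for Slc6a19, an amino acid transporter. The largest falls were all in genes listed at 0 in CAM. In M-CSF these stood at 82.9 CPM for Clec10a, a lectin of alternatively activated macrophages, 56.7 for Samd4, 47.1 for Wash1, 40.2 for Muc6, 33.1 for Eif1, 31.2 for Cd200r1, 30.1 for Leprot, 25.6 for Slco2b1, 24.9 for Rogdi and 22.8 for P2ry12. Eif1 and Mcl1 are expressed by most cells, so a listed 0 cannot be read as absence. DESeq2's Wald test did not call Clec10a (adjusted p = 0.2) or Leprot (adjusted p = 0.283).

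In total, 6269 of 14104 tested genes passed the threshold of the edgeR quasi-likelihood test between CAM and M-CSF, 3024 higher and 3245 lower in CAM, and 6732 differed by at least 2-fold (3023 higher, 3709 lower). The columns carry the number 2 for M-CSF and 1 for CAM, which no label explains, and with a block on the column numbers, which the peptide libraries tie together and which leaves no test, 7063 genes differed by at least 2-fold. DESeq2's Wald test called 3473, and with library size only as the scaling 28.5% of calls were higher in CAM, against 48.2% with TMM. Without a filter on low counts 10253 genes differed by at least 2-fold.

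**Figure D1:**
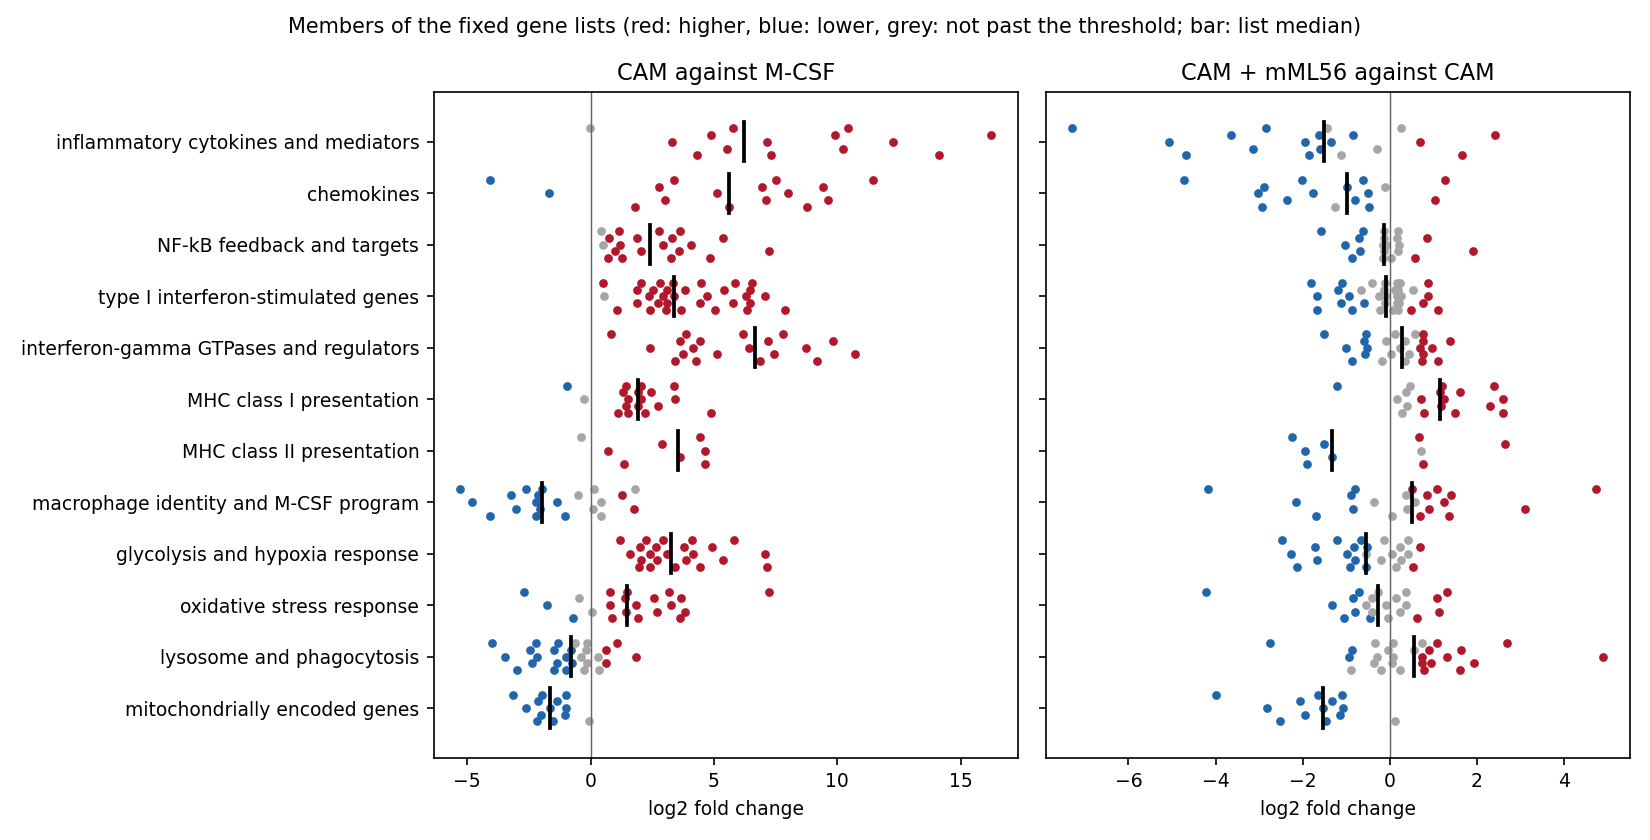
Log2 fold changes (x axis) of the tested members of 12 gene lists (y axis), on the left for CAM against M-CSF (234 genes drawn, 13 left out because a group was at 0) and on the right for peptide-treated CAM against CAM (245 drawn, 2 left out). Each point is a gene, red where it was higher and blue where it was lower past the threshold and grey where it was not past it, and a black bar is the list median with genes at 0 at their bound; cytokine and chemokine medians lie at 6.2 and 5.61 on the left and at -1.52 and -0.99 on the right.

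The comparison of peptide-treated CAM with CAM was the main question of the series. Many cytokine, mediator and chemokine genes were lower with the peptide, while 12 of 18 MHC class I genes were higher and interferon-induced genes moved both ways. Il12b went from 719.6 CPM in CAM to 4.59 ± 1.67 CPM (SD, n = 2), a log2 fold change of -7.29 (SE 0.235, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.66e-09), against a listed 0 in M-CSF. Ptgs2 went from 17770 to 4620 ± 569 CPM (log2 fold change -1.94, SE 0.237) and Nos2 from 15950 to 6306 ± 597 CPM (-1.34, SE 0.238), both far above their M-CSF levels. Saa3, an acute-phase protein, rose from 1274 to 6815 ± 593 CPM (2.42, SE 0.251), against 7.91 CPM in M-CSF.

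Among 20 cytokine and mediator genes, 12 fell and 4 rose (13 and 4 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 0.0108, and adjusted p = 0.874 with an estimated correlation). Il1b, the fever-inducing cytokine, stood at 18.6 CPM in CAM and 0.172 and 0.915 CPM in the peptide libraries, and was listed at 0 in M-CSF. Il18 rose from 6.39 to 20.1 CPM in both peptide libraries, a log2 fold change of 1.65 (SE 0.296). Among 17 chemokines 12 fell and 2 rose (12 and 3 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 0.0108, and adjusted p = 0.874 with an estimated correlation). With the offset for length and GC content 9 chemokines fell and 2 rose (median -0.696). Of the cytokine and mediator genes 14 fell and 4 rose with that offset (median -1.5). Cxcl2, which attracts neutrophils (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), went from 203.3 to 7.73 ± 0.83 CPM (log2 fold change -4.71, SE 0.188), and Ccl3, which attracts monocytes, from 527.3 to 64.6 ± 0.774 CPM (-3.03, SE 0.156), close to the 50.4 CPM of M-CSF. Ccl5, a chemokine for T cells, went the other way, from 2662 to 6439 ± 261 CPM (1.27, SE 0.233). Among 20 NF-kB feedback and target genes 6 fell and 3 rose, the same adjusted over the list alone, or 5 and 1 with the offset for length and GC content. Nfkb1, the p50 precursor, fell from 430.9 to 144.8 ± 18 CPM, and Nfkb2, the p52 precursor, rose from 28.3 to 105.8 ± 3.75 CPM.

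Of 33 type I interferon-stimulated genes 5 rose and 9 fell, the same adjusted over the list alone, and of 24 IFNγ-induced GTPases and regulators 8 rose and 7 fell (10 and 7 adjusted over the list alone), or 10 and 4 with the offset and 11 and 6 with library size only. Neither list passed camera (adjusted p = 0.507 and 0.621). Irf7, a transcription factor of the interferon response, rose from 579.6 to 1246 ± 46.5 CPM, and Irf1 from 925.5 to 2007 ± 156 CPM, while Oasl1 fell from 584.6 to 184.3 ± 11.7 CPM. MHC class I genes rose in 12 of 18 cases and fell in 1 (14 and 1 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 0.000504, and adjusted p = 0.874 with an estimated correlation). H2-K1 was at 273.1 CPM in CAM and 1661 ± 212 CPM with the peptide, and H2-Q6 at 216.8 and 1314 ± 80.2 CPM, values that reads shared among near-identical class I genes make uncertain. Nlrc5, a transactivator of class I genes, was the member that fell, from 60.5 CPM to 17.7 and 34.7 CPM. MHC class II genes rose in 3 and fell in 5 of 9 cases, the same adjusted over the list alone, or 1 and 5 with the offset. Ciita, their transactivator, fell from 81.9 to 28.5 ± 0.687 CPM and H2-Eb1 from 163.3 to 42.4 ± 5.87 CPM.

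Macrophage identity genes rose in 10 of 21 cases and fell in 6, and lysosome and phagocytosis genes rose in 12 of 27 and fell in 3 (14 and 3 adjusted over the list alone; the first list was the same). Neither list passed camera (adjusted p = 0.454 and 0.181). With the offset for length and GC content 7 macrophage identity genes rose and 6 fell. Of the lysosome genes 9 rose and 3 fell with that offset (median 0.255, against 0.563 without it). Cebpa rose from 0.65 to 17.7 ± 1.32 CPM, against 18.3 in M-CSF, and Folr2, a folate receptor of tissue macrophages, from 8.12 to 70.1 ± 6.78 CPM, against 76.7 in M-CSF. Cx3cr1, the fractalkine receptor, fell from 34.3 to 1.90 ± 0.612 CPM and Apoe, the lipid carrier, from 1434 to 324.5 ± 15.7 CPM, both below their M-CSF levels of 25.9 and 6559 CPM. Cd68 rose from 1.19 to 35.9 ± 4.33 CPM, and Ctsh, a lysosomal protease, from 114.6 to 741.5 ± 111 CPM. Alternative activation markers rose in 3 and fell in 6 of 20 cases (3 and 7 adjusted over the list alone): Klf4, a transcription factor, rose from 103.6 to 449.2 ± 31 CPM and Ccl22 fell from 21.1 to 1.95 ± 0.286 CPM. Lipid-handling genes rose in 8 and fell in 4 of 22 cases (8 and 5 adjusted over the list alone), with Pltp at 2.17 CPM in CAM and 31.8 ± 0.248 CPM with the peptide.

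Glycolysis and hypoxia-response genes fell in 13 of 24 cases and rose in 2 (4 with library size only), the same adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.0456, and adjusted p = 0.874 with an estimated correlation). Adm, the hypoxia-induced peptide adrenomedullin, fell from 62.0 to 12.9 ± 4.98 CPM. Nuclear genes of oxidative phosphorylation rose in 13 of 27 cases and fell in 0 (15 and 0 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.0108, and adjusted p = 0.874 with an estimated correlation). Mitochondrially encoded genes went the opposite way, with 12 of 13 lower, the same adjusted over the list alone, and a median of -1.53 (camera adjusted p = 0.000103, and adjusted p = 0.874 with an estimated correlation). mt-Nd3 fell from 29.4 to 4.15 ± 0.339 CPM, while mt-Co1, the most abundant of them in CAM, was at 8079 CPM in CAM and at 10660 and 7032 CPM with the peptide, not past the threshold (edgeR adjusted p = 0.757). Oxidative stress genes rose in 4 and fell in 7 of 21 cases, the same adjusted over the list alone (6 and 6 with library size only), and Slc7a11 fell from 1772 to 94.6 ± 3.22 CPM (log2 fold change -4.23, SE 0.171).

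Among Ninj1, adhesion and metalloproteinase genes 4 rose and 11 fell of 29, the same adjusted over the list alone. Mmp13 fell from 575.7 to 36.7 ± 1.63 CPM and Mmp12, an elastase of macrophages, from 292.6 to 31.5 ± 2.77 CPM, while Selplg, the selectin ligand, rose from 92.5 to 437 ± 9.49 CPM. Ninj1 was at 44.6 CPM in CAM and 54.1 ± 0.767 CPM with the peptide, a log2 fold change of 0.28 (SE 0.184) not past the threshold (edgeR adjusted p = 0.255). Inflammasome and lytic death genes rose in 7 and fell in 3 of 18 cases (8 and 3 adjusted over the list alone). Gsdmd, the pore former of pyroptosis, rose from 73.2 to 283.9 ± 14.4 CPM and Nlrp3, an inflammasome sensor, fell from 547.9 to 149.2 ± 3.81 CPM. Counts that rose and fell were 3 and 2 of 12 for heat shock (5 and 1 with library size only), where Hspa8 rose from 144.8 to 1293 ± 73.4 CPM, and 4 and 7 of 25 for cell cycle, where E2f1 rose from 6.28 to 31.5 ± 0.0782 CPM and Cenpf fell from 10.9 to 1.27 ± 0.089 CPM. They were 5 and 3 of 21 for unfolded protein stress, 4 and 5 of 18 for cholesterol synthesis, 5 and 5 of 18 for immediate early genes (6 and 5 adjusted over the list alone) and 3 and 5 of 21 for PI3K, insulin and FoxO targets (5 and 6 adjusted over the list alone), but 4 and 6, 4 and 2, 2 and 7, and 5 and 4 with the offset. Histones rose in 4 and fell in 1 of 7 (4 and 2 adjusted over the list alone). None of these lists passed camera.

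Markers of other cells moved in few cases. Platelet markers rose in 2 of 6, with Pf4 at 2.06 CPM in CAM and 10.2 ± 2.22 CPM with the peptide. T and NK markers fell in 2 of 6 and rose in none, with Il7r at 140.1 CPM in CAM and 54.4 ± 1.49 CPM with the peptide. That list passed camera (adjusted p = 0.0343, and adjusted p = 0.874 with an estimated correlation) but had a median of 0 without the filter on low counts and then did not pass (adjusted p = 0.414). Dendritic cell markers fell in 3 of 7, among them Ccl22, neutrophil markers in 1 of 4 and erythroid markers in 1 of 2 (0 with library size only). Fibroblast and endothelial markers rose in 2 and fell in 1 of 10, and no B cell marker of 4 and no basophil or mast cell marker of 2 passed the threshold. Adjusted over the list alone, these counts were the same.

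**Figure D2:**
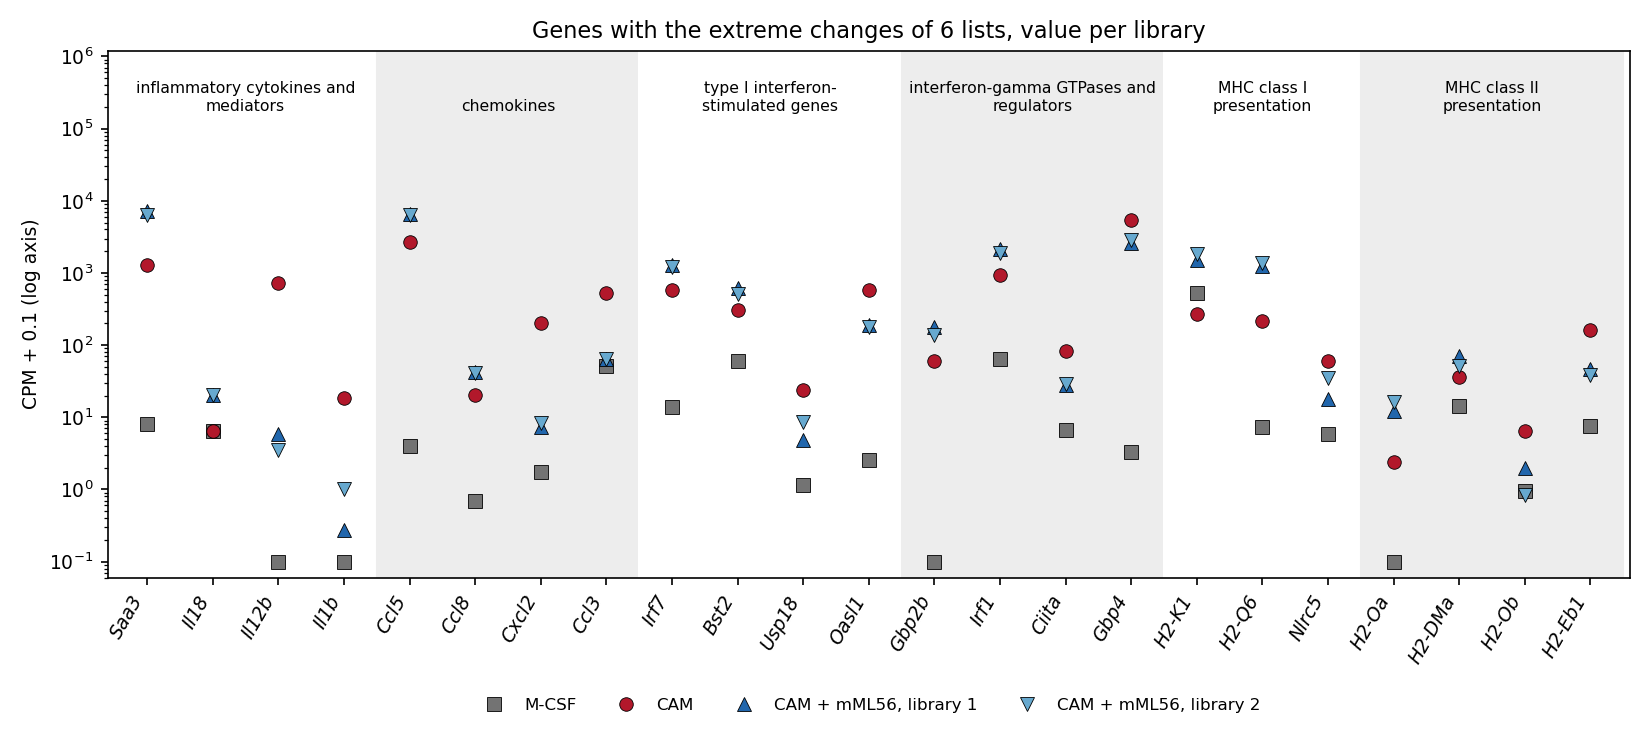
Expression of 23 genes from 6 gene lists in each of the 4 libraries, in CPM plus 0.1 on a log axis. The pair of peptide points lies close together for most genes; Il12b falls from 719.6 CPM in CAM to 5.76 and 3.41 CPM, and Saa3 rises from 1274 to 7234 and 6396 CPM.

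The largest rises by the fixed rule were all in genes listed at 0 in CAM. Eif1, a translation initiation factor, was at 33.1 CPM in M-CSF and at 47.8 and 60.9 CPM with the peptide, and Wash1 at 47.1, 17.6 and 10.1 CPM. In the same order, Tti1 was at 5.06, 19.4 and 31.8 CPM, Usp8 at 9.01, 20.99 and 23.7, Plagl2 at 6.35, 12.7 and 14.6, Kars at 1.75, 8.60 and 16.2, Etv5 at 1.30, 14.2 and 8.65, Abca8b at 0, 12.65 and 9.81, Ltc4s at 12.7, 8.35 and 12.3, and Tmem192 at 2.46, 10.4 and 9.64. The largest falls, besides Il12b, Il1b and Cxcl2, included Rnf41, at 18.5 CPM in CAM and listed at 0 in the other 3 libraries. Stk3 went from 12.02 to 0.08603 and 0.08315 CPM, Tmeff1 from 10.8 to 0.2581 and 0.1663 CPM, and Csf3, the neutrophil growth factor, from 11.1 to 0.2581 and 0.582 CPM. Itgb8, an integrin chain that activates TGF-β, fell from 37.3 to 1.09 ± 0.811 CPM and Lox, a collagen cross-linking enzyme, from 31.6 to 1.10 ± 0.385 CPM. Actg1, a cytoplasmic actin with many pseudogenes, was at 55.7 CPM in CAM and 2.28 ± 0.0551 CPM with the peptide, against 2.4 CPM in M-CSF, a value that shared reads make uncertain.

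In total, 5320 genes passed the threshold of the edgeR quasi-likelihood test between peptide-treated CAM and CAM, 2904 higher and 2416 lower with the peptide, and in 5317 of them both peptide libraries lay on the same side of CAM. Of 5210 genes that differed by at least 2-fold on average, 2848 were higher and 2362 lower, and 2198 and 1717 genes were at least 2-fold higher or lower in both peptide libraries. DESeq2's Wald test called 2349 genes, and without a filter on low counts 9039 genes differed by at least 2-fold. CAM was a lone library, so a difference in its culture or preparation stands on the same axis as the peptide.

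The direction of the peptide difference was then set against that of activation. Of the 3024 genes higher in CAM than in M-CSF, 1286 (42.5%) were lower with the peptide, where lists of independent genes would share 518, and 308 (10.2%) were higher again, where 622.6 would be shared. Of the 3245 genes lower in CAM, 1606 (49.5%) were higher with the peptide, against 668.1, and 166 (5.12%) were lower again, against 555.9. Il12b, Cxcl2 and Nfkb1 were among those that rose and then fell, Cebpa, Folr2 and Selplg among those that fell and then rose, Saa3, Irf1 and Klf4 rose in both, and Apoe and mt-Nd3 fell in both. Simulated unchanged libraries, in which no gene was made to differ, gave means of 0 and 0.01 genes for the opposite classes, and the independent values leave out the shared CAM library, so neither measures how far that library raised the overlap. Across the 14104 genes the covariance of the effects was -3.24 on the squared log2 scale, against -0.303 ± 0.0154 (SD, 100 simulations) in the simulated libraries, a difference of -2.94. Pearson's r was -0.663, against a simulated -0.667. The simulated libraries varied like the peptide pair and the CAM library could not be split, so part or all of the difference may come from its use in both comparisons, and with a prior count of 2 the covariance was -1.34.

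**Figure D3:**
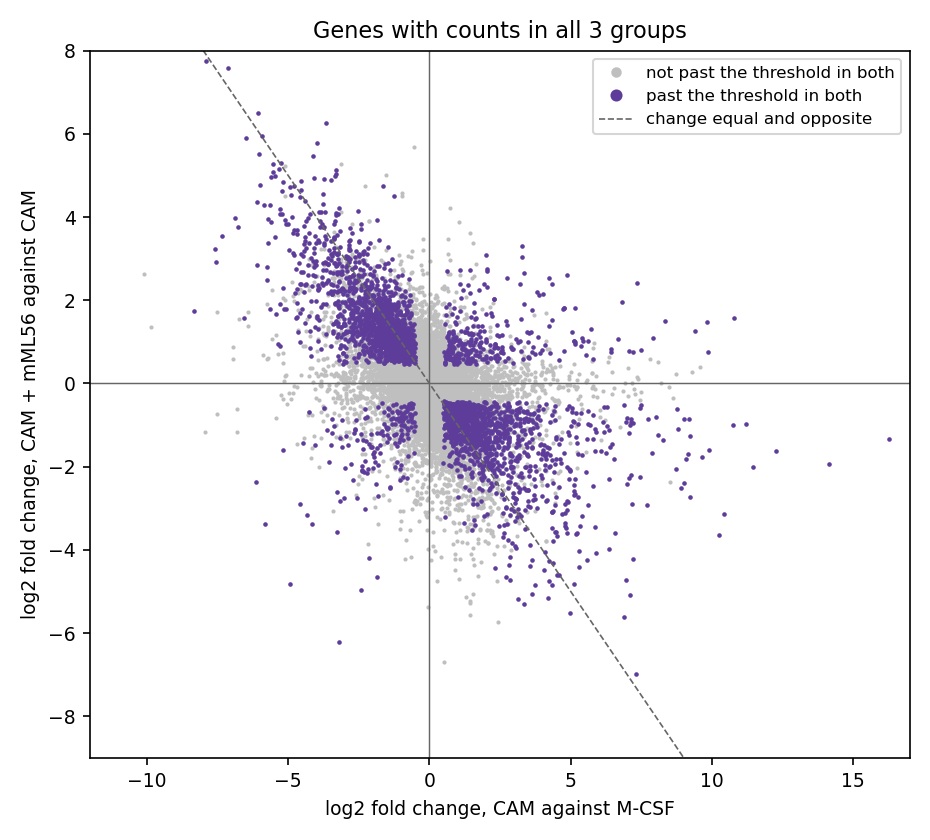
Log2 fold change of CAM against M-CSF (x axis) and of peptide-treated CAM against CAM (y axis) for 13132 genes with counts in all 3 groups. Of the 3049 genes past the threshold in both comparisons, 2595 lie in the quadrants of opposite sign, and the dashed line marks equal and opposite changes.

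Peptide-treated CAM were also compared with M-CSF macrophages, which shows how far they lay from unactivated cells. Some genes that activation changed stayed far above M-CSF with the peptide and others lay near it. Among the latter Il1b still passed the threshold of the edgeR test. Its listed 0 in M-CSF makes that fold change depend on the prior count. Nos2 was at 6306 ± 597 CPM (SD, n = 2) against 0.1945 CPM, Ptgs2 at 4620 ± 569 against 0.972 CPM (log2 fold change 12.20), and Saa3 at 6815 ± 593 against 7.91 CPM (9.75, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.48e-10). Folr2, at 70.1 ± 6.78 against 76.7 CPM, and Ccl3, at 64.6 ± 0.774 against 50.4 CPM, were not past the threshold (edgeR adjusted p = 0.595 and 0.11), and Il1b, listed at 0 in M-CSF, was at 0.172 and 0.915 CPM.

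Cytokine and mediator genes were higher than in M-CSF in 19 of 20 cases, with a median of 6.26, or 5.02 with members at 0 at their bound, and chemokines were higher in 11 and lower in 2 of 17 (median 2.68). All 24 IFNγ-induced genes (median 6.61) and 32 of 33 type I interferon-stimulated genes (median 3.31) were higher, as were 18 of 18 MHC class I genes (median 2.70), 7 of 9 class II genes (median 2.12), 15 of 20 NF-kB genes (17 adjusted over the list alone, median 2.34) and 23 of 24 glycolysis genes (median 2.63). Camera gave adjusted p = 3.72e-11, 0.00012, 1.68e-16, 3.76e-16, 4.6e-10, 0.000492, 2.03e-08 and 3.5e-11 in that order, and adjusted p = 0.694 with an estimated correlation for each. Inflammasome genes were higher in 12 and lower in 3 of 18 cases (median 1.54; camera adjusted p = 0.00331, and adjusted p = 0.694 with an estimated correlation). Oxidative stress genes were higher in 15 and lower in 2 of 21 (16 and 2 adjusted over the list alone, 13 and 4 with library size only, median 1.86), and heat shock genes higher in 9 and lower in 1 of 12 (median 1.51). All 13 mitochondrially encoded genes were lower (median -3.58), with mt-Nd3 at 4.15 ± 0.339 against 262.7 CPM. For these 3 lists camera gave adjusted p = 0.000207, 0.000678 and 3.23e-07, and adjusted p = 0.785 with an estimated correlation. Counts not given a second value were the same adjusted over the list alone.

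Macrophage identity genes were lower in 11 and higher in 3 of 21 cases (11 and 4 adjusted over the list alone, 13 and 1 with library size only), which did not pass camera (adjusted p = 0.0775). Alternative activation markers were lower in 11 and higher in 7 of 20 (11 and 9 adjusted over the list alone); Cd163, a scavenger receptor, was at 71.1 CPM in M-CSF, 2.92 in CAM and 0.379 ± 0.17 CPM with the peptide. Lysosome genes were lower in 11 and higher in 6 of 27 (12 and 6 adjusted over the list alone). In total, 5804 genes passed the threshold, 3124 higher and 2680 lower in peptide-treated CAM, and 5430 differed by at least 2-fold (2588 higher, 2842 lower). DESeq2's Wald test called 3279, 33.2% of calls were higher with library size only against 53.8% with TMM, and 9125 genes differed by at least 2-fold without a filter on low counts.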

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

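The fit without Lars2 and Gm15662, the offset for length and GC content, the thinning and the block on column numbers were chosen after the data were seen, and the other alternatives before. No named gene past the threshold changed direction with DESeq2 size factors, library size only, DESeq2's Wald test or the offset. None did so when either peptide library was left out of the comparison with CAM. No list past its threshold changed direction with DESeq2 size factors, with library size only, without the filter or without either peptide library. Directions of named genes and lists were not checked under the other alternatives. Among all genes, 3995 of the 3996 called both with and without the offset for peptide against CAM had the same direction. DESeq2's Wald test called fewer genes than edgeR, 3473 for CAM against M-CSF, 2349 for peptide against CAM and 3279 for peptide against M-CSF, of which 3465, 2342 and 3274 were also called by edgeR, and 56.5%, 60.4% and 64.8% of its calls were higher, against 48.2%, 54.6% and 53.8%; the cause was not tested. The other alternatives kept these counts within 1.5 times of 6269, 5320 and 5804: with DESeq2 size factors they were 6505, 5545 and 6025, with no filter 5565, 4544 and 5199, with library size only 6831, 5101 and 6218, with robust empirical Bayes 6188, 5291 and 5776, without Lars2 and Gm15662 6261, 5315 and 5803, with thinning 6121, 5085 and 5620, and with the offset 6118, 4674 and 5780. With only the libraries of the groups compared, the peptide comparisons gave 5643 and 5901. Scaling by library size only moved the median log2 fold change of all genes from -0.0741 to -0.55 for CAM against M-CSF, from 0.0453 to 0.132 for peptide against CAM and from -0.0755 to -0.464 for peptide against M-CSF, and the share of calls that were higher to 28.5%, 61.2% and 33.2%. Under that scaling the medians of the cholesterol, cell cycle, immediate early, fibroblast and histone lists changed sign for CAM against M-CSF, those of the type I interferon, Ninj1, dendritic and fibroblast lists for peptide against CAM, and that of oxidative phosphorylation for peptide against M-CSF.

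Without a filter on low counts, 10253, 9039 and 9125 genes differed by at least 2-fold, more than with it because low-count genes were then included. The covariance of the effects was -3.82 without the filter and -1.34 with a prior count of 2, which shrinks the fold changes of low-count genes, and lay between -3.23 and -3.14 when either peptide library was left out. With an estimated correlation, camera called 0 of the 32 lists in CAM against M-CSF, 0 in peptide against CAM and 0 in peptide against M-CSF. With the preset correlation it called 15, 7 and 12. The estimated setting tests each list on the residual degrees of freedom, here 1, so hardly any list could pass. For CAM against M-CSF the MHC class II list had an estimated correlation of 0, below the preset 0.01, and still did not pass. The adjusted p-values with an estimated correlation thus decide nothing for or against a list. With 1 residual degree of freedom such correlations are also poorly determined. Without either peptide library the counts of genes at least 2-fold apart ranged from 5184 to 5475 against CAM and from 5355 to 5909 against M-CSF, and no test remained because no residual degree of freedom was left. Each list median was compared with its 2 values with a peptide library left out. In these comparisons 14 medians without library 1 and 16 without library 2 moved by more than the SD of those 2 values. The other 50 and 48 did not. A median midway between the 2 values always lies within that SD, so the 50 and 48 say little about how far the libraries differ. For peptide against CAM the cell cycle median went from -0.138 to 0.153 and the immediate early median from -0.105 to 0.0775 without library 2. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. A block on the numbers in the column names left no residual degree of freedom and gave 7063, 5475 and 5355 genes at least 2-fold apart. The 5475 is the count against CAM without library 2, and the 5355 is the count against M-CSF without library 1. For the peptide comparisons the block therefore adds no further check. Among named genes, DESeq2's Wald test left 205 on the same side of the threshold and lost 30, leaving out genes without an adjusted p. The offset left 242, lost 10 and added 3, and library size only left 245, lost 8 and added 2. The genes left on the same side include some that were not past the threshold in the main test. The totals of 10334062 to 12842750 limit what can be said of genes below about 1 CPM, where a library holds few counts.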

Other observations

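Besides the fixed lists, 24 gene families defined by symbol were counted in both main comparisons. Genes of cytosolic ribosomal proteins fell on activation in 66 of 92 cases and rose in 8 (Fisher's exact test against all other tested genes, adjusted p = 3.52e-21 over 96 tests), and with the peptide 39 rose and 6 fell (adjusted p = 5.89e-05). Complex I subunits of the respiratory chain fell on activation in 20 of 36 cases and rose in 1 (adjusted p = 0.00033), and with the peptide 16 rose and 0 fell (adjusted p = 0.0104). Mitochondrial ribosomal proteins rose with the peptide in 29 of 79 cases and fell in 4 (adjusted p = 0.00955), and cathepsins, the lysosomal proteases, rose in 8 of 14 and fell in 1 (adjusted p = 0.0164). Proteasome subunits rose on activation in 32 of 48 cases and fell in 2 (adjusted p = 9.46e-10), as did 7 of 7 Schlafens (adjusted p = 0.00033) and 8 of 12 PARPs with 2 that fell (adjusted p = 0.0091). Cd300 receptors fell on activation in 8 of 10 cases and rose in 2 (adjusted p = 0.00267), and with the peptide 6 rose and 1 fell (adjusted p = 0.0322). With the offset for length and GC content the peptide counts were 27 up and 8 down for cytosolic ribosomal proteins, 23 and 5 for mitochondrial ones, 11 and 0 for complex I, 5 and 1 for cathepsins and 7 and 1 for Cd300 receptors. For the families and comparisons named here, the direction was the same with library size only and with DESeq2 size factors. Fisher's exact test took genes as its units, so its p-values measure no spread between libraries. Genes of a family are not independent, and ribosomal protein genes share sequence with pseudogenes.

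Of the tests that follow, the permutation of genes between lists, the percentile of the interferon lists and the count of genes that overlap another were chosen only after the result was seen, as were the families.

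CAM differed from the peptide libraries in 5320 genes by the edgeR test. No test was run between the peptide libraries. Of 7376 genes at a mean of at least 10 CPM, 84 lay at least 2-fold apart between them. By the same measure 1822 and 1718 did between CAM and peptide libraries 1 and 2. Length and GC content bias as the whole cause is argued against by the 4674 calls that the fit with an offset for both still made, of which 3996 were among the 5320, and the lower depth of CAM by the 5085 calls made after thinning. In 81.18% of the calls CAM lay outside the range of the other 3 libraries, against 52.72% among other genes. In 5317 of the calls both peptide libraries already lay on the same side of CAM, so the share among other genes is not a baseline. The share of 81.18% would be high if the peptide returned genes toward their unactivated level, and also if the CAM culture or library stood apart for another reason. With 1 CAM library these cannot be told apart, and the peptide stays an open explanation.

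The median log2 fold change with the peptide was -1.338 over 37 cytokine, mediator and chemokine genes and 0.1094 over 57 interferon-induced genes, a difference of -1.448. Random splits of these genes gave p = 1e-05 (two-sided permutation, the smallest that 100000 draws can give), which decides nothing, since genes regulated together are not independent and all were set against 1 CAM library. With the offset for length and GC content the difference was -1.568, which argues against that bias. Genes raised as far over M-CSF as the cytokine and chemokine genes had a matched median of -0.8095. The lists' own median lay at percentile 7.51 of such random lists. The cytokine and chemokine genes thus fell further than most matched lists, but not past the limit set beforehand. Their fall may in part be a chance excess of the lone CAM library. The interferon genes lay at percentile 100 of lists matched in the same way (matched median -0.9111). The matched lists drew genes singly and ignored expression level and shared regulation. The percentile therefore does not settle whether a chance excess of CAM played a part. An effect of mML56 and another difference of the CAM culture both stay open.

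Eif1 and Wash1 were listed at 0 in CAM with at least 10 CPM in each of the other 3 libraries. Poisson counts at the depth of CAM predicted 6.863e-42 such genes. The level of at least 10 CPM that the rule asks for makes this number tiny beforehand. Counting chance is thus argued against by that level, and the prediction is no separate test. The same rule gave 16 genes at 0 in M-CSF, but there it also takes in genes that activation raised. Among them was Upp1, at 320.6 CPM in CAM and 341.2 and 352.4 CPM with the peptide. The rule gave 1 gene in peptide library 1 and 0 in peptide library 2, a mean of 0.5. The counts of the CAM and peptide libraries are too few to decide whether the assignment of reads to genes may vary between libraries. Overlap with another gene is argued against as far as GENCODE M21 goes, where 0 of the 2 overlapped one on either strand; the annotation release used upstream is not given in the sources used here. Tnf, listed at 0 in every library, had no such contrast.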
